A study of Mus musculus with 26 samples.

How the data were processed

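RNA-seq was carried out in mouse embryonic stem cells (ESCs) in which ERR beta, the orphan nuclear receptor encoded by Esrrb, had been knocked out, and in the same cells carrying a doxycycline-inducible construct. Per the labels' protocols, 1600 cells were seeded on poly-L-ornithine and laminin and treated with doxycycline at 2 µg/ml for 3 days. The study design text gives the medium as N2B27 with PD and CH (inhibitors of MEK and GSK3), while the growth protocol adds LIF, so the presence of LIF is not settled by the labels. Total RNA was depleted of ribosomal RNA, made into strand-specific libraries and sequenced as single-end reads of 100 bp on a NovaSeq instrument, per the labels' protocols. Each of 7 groups held 2 independently established clones. Each clone gave 2 libraries, except the clones carrying ERR gamma (Esrrg), which gave 1 library each, for 26 libraries from 14 clones. The clone was the unit of replication, so n = 2 in every group.

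The authors aligned reads with STAR (version 2.7.8a) to mm10, per the submitters' processing notes. The deposited table holds integer read counts per gene symbol made with featureCounts, whose version was 2.0.1 per the file headers and 2.0.10 per the submitters' processing notes. Per the file headers, reads were counted over exons on the reverse strand, a read lying in overlapping genes was counted for each of them, and reads that aligned to several places were not counted. Genes of multi-copy families are therefore undercounted by an unknown amount. Of 294 named genes and list members, 10 shared exonic bases with another gene on the same strand. The shared part was 94.8% of Cpt1b (with the read-through gene of Chkb and Cpt1b) and 92.8% of Eno1 (with Eno1b), and at most 7.24% in the others. The gene counts do not separate transcripts of the endogenous Esrrb gene from transcripts of a construct. The table held 24421 genes, none of them from the mitochondrial genome, and every one of its 26 count columns was used.

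Library totals, computed as the sum of the deposited counts, ran from 21276790 to 30021667. Clone totals, after adding the libraries of each clone, ran from 25103562 to 54105869 counts. The ribosomal gene Rn45s took 1.19% to 3.22% of a library and was kept in the totals. A gene with 0 counts was given an upper limit of 3 counts over the group's total. Such limits cover counting error only, since reads amplified by PCR are not independent molecules.

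Genes were tested with edgeR (version 4.0.16) in R (version 4.3.3). Counts of the 2 libraries of a clone were summed, genes with too few counts were removed with filterByExpr, TMM factors were computed (0.972 to 1.05), and a robust quasi-likelihood model with 1 mean per group was fitted to all 14 clones together. It tested 15238 genes with 7 residual degrees of freedom, a median of 4.28 prior degrees of freedom and a biological coefficient of variation of 0.116. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. The p-values measure the spread between clones, and with 2 clones per group they carry whatever set the clones of a group apart, including how and when each clone was made. Fold changes are log2 with a prior count of 0.125, each given with its standard error, computed as the absolute log2 fold change over the square root of the F statistic. Levels are CPM, counts scaled to a common library total, with the standard deviation (SD) of the 2 clones. CPM of Esrrb, Esrrg and Esrra used library totals, and CPM of all other genes used TMM-scaled totals.

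Before the data were examined, 11 comparisons were chosen: the knockout with the empty construct (KO_mock) against wild-type cells with the empty construct (WT_mock), wild-type ERR beta in the knockout (KO_ERRb_wt) against each of them, and the DNA-binding deficient (KO_ERRb_DBDm3), TFIIH-binding deficient (KO_ERRb_DBDm6) and coactivator-binding deficient (KO_ERRb_AF2M6) mutants and ERR gamma (KO_ERRg_wt) each against KO_mock and KO_ERRb_wt. Comparisons of KO_ERRb_DBDm6, KO_ERRb_AF2M6 and KO_ERRg_wt against KO_ERRb_DBDm3 were added after chromosome-wide shifts had been seen. The list tests, the count of restored genes and most alternatives were also chosen before. The chromosome settings, the smaller set of restored genes and the exclusion of chromosomes 6, 8 and 14 were chosen afterwards.

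The named genes followed a rule. Esrrb and Esrrg were always given. Among called genes with a mean log2 CPM of at least 1 and both clones of a group above both clones of the other, the 10 highest and 10 lowest fold changes were named for KO_mock against WT_mock and for KO_ERRb_wt against KO_mock, and the 5 highest and 5 lowest for every other comparison, passing over unnamed predicted genes and ribosomal RNA. Some genes meeting these rules are not reported here. Up to 4 members with the smallest p were named for each list described.

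The 24 gene lists were written from general knowledge before the data were examined: naive pluripotency, general pluripotency, formative and primed pluripotency, trophoblast, primitive endoderm, mesoderm, neuroectoderm, 2-cell-like state, germline, fibroblast feeder, ERR family and cofactors, TFIIH subunits, nuclear and mitochondrial OXPHOS, TCA cycle, fatty acid oxidation, glycolysis, Wnt targets, FGF-MAPK targets, LIF-STAT3 targets, p53 targets, integrated stress response (ATF4), cell cycle and replication, and imprinted genes. The mitochondrial OXPHOS list had 0 of its 13 members measured, so 23 lists were tested. They were tested with camera in limma (version 3.58.1) on log2 CPM (prior count 2) of the clones with an inter-gene correlation of 0.01, with adjustment over the 23 lists of a comparison. The same test with an estimated correlation and the rotation test fry were run beside it. Called members are counted once with p-values adjusted over all genes and again with p-values adjusted over the list alone.

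Restoration was counted within the genes called in KO_mock against WT_mock as those called in the opposite direction in a construct against KO_mock. Because both comparisons share the KO_mock clones, the count was set beside 20 simulated data sets in which constructs did not differ from KO_mock, beside the count 2 independent lists of the same sizes would share, and beside a fit in which 1 KO_mock clone defined the genes and the other served as the reference. Chromosome shifts were centred median log2 CPM differences from WT_mock over genes with mean log2 CPM above 3.

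The scripts were tested on simulated data for KO_mock against WT_mock with 50 changed genes at each fold size. They recovered 17 of 50 genes at 1.5-fold with a mean absolute error of 0.156 log2, 50 of 50 at 2-fold (error 0.141), 50 of 50 at 4-fold (error 0.16) and 50 of 50 at 8-fold (error 0.173). Of 14728 unchanged genes 4 were called, and 0 were called where nothing differed.

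Alternatives tried were each library as a replicate, limma-voom with the clone as a random effect, DESeq2 (version 1.42.0), RLE size factors, no low-count filter, a fit of only the 2 groups compared, replicate numbers as blocks, each clone left out in turn, a minimum absolute log2 fold change of 1, the KO_mock clones split, and for lists the estimated correlation, camera on the 26 libraries, RLE factors and each clone left out. Figures were drawn in Python (version 3.11.15) with matplotlib (version 3.10.9).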

Results

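RNA-seq counts were collected from 26 libraries of mouse ESCs in 7 groups of 2 clones each. WT_mock cells carried an empty construct, and the other 6 groups were Esrrb knockout cells carrying an empty construct (KO_mock), wild-type ERR beta (KO_ERRb_wt), ERR beta deficient in DNA binding (KO_ERRb_DBDm3), in TFIIH binding (KO_ERRb_DBDm6) or in coactivator binding (KO_ERRb_AF2M6), or wild-type ERR gamma (KO_ERRg_wt). TFIIH is the general transcription factor that opens promoters and phosphorylates RNA polymerase II. Each clone gave 2 libraries, or 1 in the KO_ERRg_wt group. The library totals ran from 21276790 to 30021667 counts. Values in parentheses after a gene are its log2 fold change ± standard error with n = 2 clones per group, and levels are CPM ± SD of the 2 clones.

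Esrrb (mm10 chromosome 12, 86361117 to 86521628, plus strand, 14 exon entries) encodes the orphan nuclear receptor that the study removed and put back. Its level was 605 ± 37.1 CPM in WT_mock (562 to 636 across its 4 libraries) and 274 ± 1.26 CPM in KO_mock (267 to 281), which is 45.3% of WT_mock, so transcripts of the locus were still read in the knockout. The level was 430 ± 19 CPM in KO_ERRb_wt (416 to 444), 510 ± 51.4 CPM in KO_ERRb_DBDm3 (472 to 553), 517 ± 25.9 CPM in KO_ERRb_DBDm6 (479 to 567) and 441 ± 18.1 CPM in KO_ERRb_AF2M6 (421 to 464). In the 2 libraries of KO_ERRg_wt it was 470 and 477 CPM, 78.3% of WT_mock, although these cells were labelled as carrying no ERR beta construct.

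Esrrg (chromosome 1, 187609006 to 188214884, plus strand, 15 exon entries) encodes ERR gamma, the close relative of ERR beta. It had 6381 counts (229 CPM) in clone 14-1-10 and 3152 counts (126 CPM) in clone 14-11 of KO_ERRg_wt, a mean of 177 ± 73.1 CPM. Every other library had 0 to 10 counts. KO_mock had 0 counts in a total of 90939451, which allows a level of up to 0.033 CPM, so Esrrg in KO_ERRg_wt was at least 5370-fold higher. Esrra (chromosome 19, 6910977 to 6921808, minus strand), which encodes ERR alpha, had group means between 24.5 and 28.2 CPM.

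**Figure D1:**
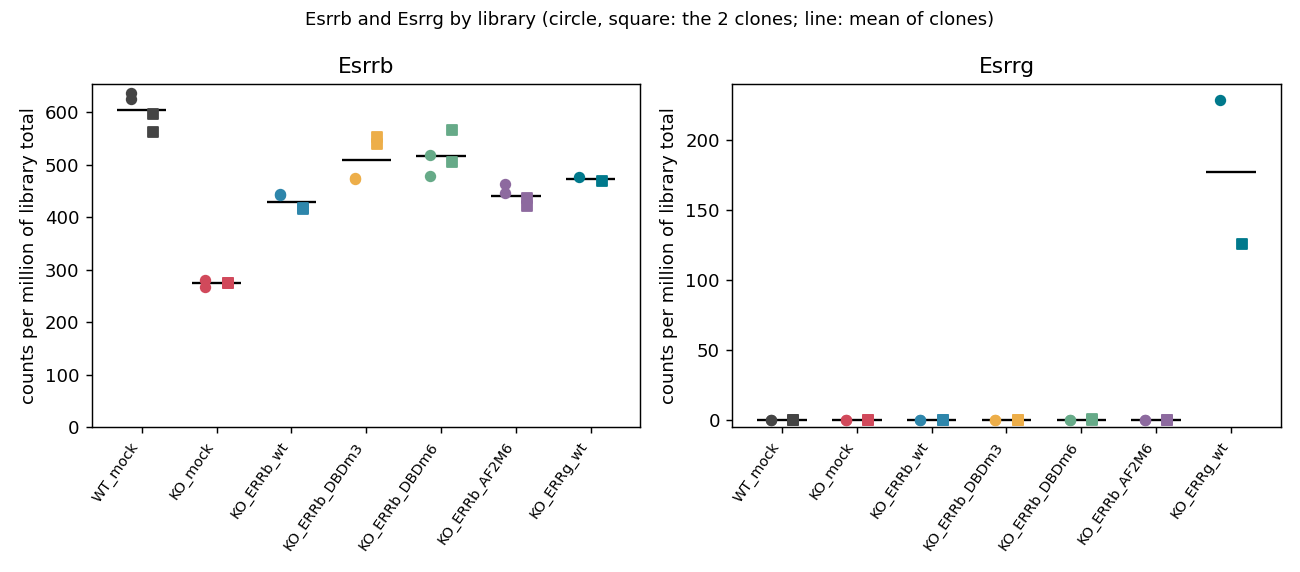
Levels of Esrrb and Esrrg in each library (CPM of the library total). Circles and squares mark the 2 clones of a group, and the line is the mean of the clones.

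Whole chromosomes differed between the groups, and this bears on every comparison that follows. Expressed genes of chromosome 14 were lower than in WT_mock in all knockout-derived groups, with a median log2 shift of −0.617 in KO_mock, −0.586 in KO_ERRb_wt, −0.569 in KO_ERRb_DBDm3, −0.516 in KO_ERRb_DBDm6, −0.567 in KO_ERRb_AF2M6 and −0.545 in KO_ERRg_wt. Genes of chromosome 6 were lower by a median log2 of −0.673 in KO_ERRb_DBDm3 (−0.416 and −0.931 in its clones), −0.923 in KO_ERRb_DBDm6, −0.94 in KO_ERRb_AF2M6 and −0.358 in KO_ERRg_wt. Genes of chromosome 8 were lower by −0.498, −0.468, −0.503 and −0.522 in the same groups. No such shift was present on chromosomes 6 and 8 in KO_mock and KO_ERRb_wt. The largest group shift of any other chromosome was 0.13, and the 2 WT_mock clones differed by at most 0.0234. Chromosomes 6, 8 and 14 carry 2046 of the 15238 tested genes (13.4%), among them Nanog, Ccnd2 and Epha1 (6), Zfp42 and Sox1 (8), and Klf5, Bmp4 and Gata4 (14).

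**Figure D2:**
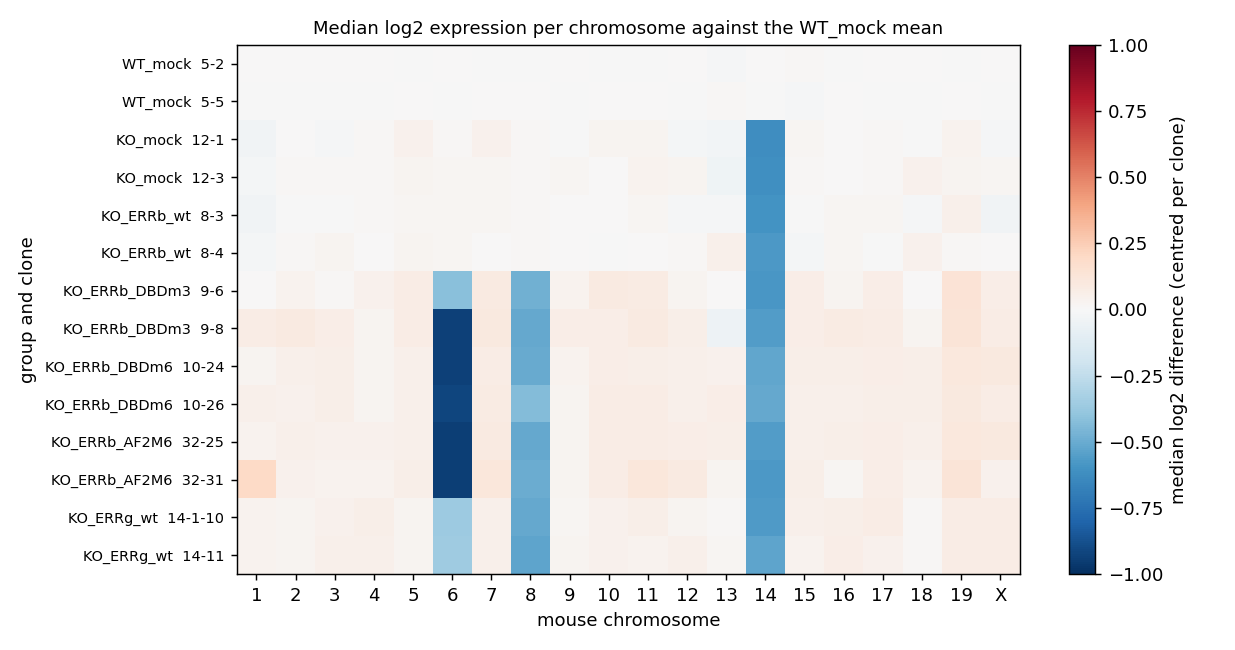
Centred median log2 difference from WT_mock of each chromosome's expressed genes in the 14 clones.

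KO_mock against WT_mock asked which genes depend on ERR beta. Without ERR beta, the fatty acid oxidation and germline lists were lower and the Wnt target and general pluripotency lists higher, none of them called with an estimated correlation (adjusted p = 0.738 with an estimated correlation for each). Cpt1b, the muscle-type carnitine palmitoyltransferase that admits fatty acids to mitochondria, fell from 16.1 ± 6.66 to 2.7 ± 0.5 CPM (n = 2 clones each). The naive pluripotency factors Nanog and Klf5 fell, and Klf5 lies on chromosome 14, which was shifted in KO_mock. Of 15238 genes, 2747 were higher and 2955 lower in KO_mock, and 479 of the higher and 1080 of the lower changed at least 2-fold. Of the called genes 856 were on chromosomes 6, 8 and 14 and 4846 elsewhere. On chromosome 14 alone, 13 genes were higher and 333 lower of 515 tested. Esrrb itself fell (−1.07 ± 0.0744, adjusted p = 3.42e-05), while Esrrg, with 2 counts in WT_mock and 0 in KO_mock, was not called (adjusted p = 0.542). Calling was repeated with each clone left out in turn, and gave 2283 genes without 5-2, 2739 without 12-1 and 3299 without 12-3.

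The largest increases among genes passing the naming rule were in Pdzrn4 (4.26 ± 0.525), a PDZ-domain ubiquitin ligase, Rimbp2 (4.24 ± 0.509), a synaptic scaffold protein, and Prickle1 (3.97 ± 0.468), a planar cell polarity protein. The interferon-inducible GTPase Irgm1 (3.57 ± 0.463) and the cyclic nucleotide phosphodiesterase Pde2a (3.26 ± 0.287) followed. Kit ligand, Kitl (3.25 ± 0.245), and the cytokine Osm (2.91 ± 0.415) of the LIF family rose as well. Others were Apol6 (3.16 ± 0.479), the hyaluronan synthase Has3 (2.91 ± 0.411) on chromosome 8, and the phospholipase-domain gene Plcxd1 (2.86 ± 0.212). The largest decreases were in Klhdc7a (−3.77 ± 0.482), a kelch-domain gene, Zc3h6 (−3.67 ± 0.528), a zinc finger gene, and the class IIa histone deacetylase Hdac7 (−3.22 ± 0.393). The muscle intermediate filament gene Des (−3.06 ± 0.363), the lysosomal enzyme Naglu (−2.99 ± 0.408) and the sodium-activated potassium channel Kcnt2 (−2.98 ± 0.4) fell too. Further decreases were in the calcium-binding S100a1 (−2.86 ± 0.71), Got1l1 (−2.69 ± 0.42) on chromosome 8, the CaMKII inhibitor Camk2n1 (−2.67 ± 0.346) and Cpt1b (−2.58 ± 0.366). Nearly all the Cpt1b exons are shared with a read-through gene, so its reads may come from either transcript. Of these 20 genes, 19 were called whichever clone was left out, and S100a1 was lost without 5-2 and without 12-1. Genes given here with a standard error had adjusted p = 3.42e-05 to 0.00996.

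Of 23 tested lists, 4 were called by camera at the assumed correlation and 0 with the estimated one. Fatty acid oxidation was lower (adjusted p = 0.0402), with 1 member higher, 8 lower and 9 not called (9 called when adjusted over the list alone, given as "alone" from here on), led by Cpt1b, Cpt1a (−1.46 ± 0.241), the rate-limiting enzyme of the pathway in most tissues, Acadl (−0.76 ± 0.162) and Cpt2 (−0.53 ± 0.121). The germline list was lower (adjusted p = 0.0402, 1 higher, 5 lower, 8 not called, 6 alone), with the RNA helicase Ddx4 (−1.06 ± 0.136), the synaptonemal protein Sycp3 (−1.35 ± 0.193) and Taf7l (−1.87 ± 0.281) lower and Hormad1 (1.19 ± 0.262) higher. Wnt targets were higher (adjusted p = 0.0402, 7 higher, 1 lower, 4 not called, 9 alone), with Dkk1 (2.84 ± 0.298), Ccnd1 (0.53 ± 0.092) and Znrf3 (0.38 ± 0.0764) higher and Bmp4 (−1.45 ± 0.224) on chromosome 14 lower. General pluripotency was higher (adjusted p = 0.0402, 6 higher, 1 lower, 8 not called, 7 alone), with Lin28a (0.89 ± 0.118), Sall4 (0.69 ± 0.108) and L1td1 (0.63 ± 0.104) higher and Dppa5a (−0.61 ± 0.118) lower. All 4 calls were lost without 12-1 (adjusted p = 0.0881 for fatty acid oxidation and 0.0694 for the other lists). They were also lost without 5-2 (adjusted p = 0.143 for fatty acid oxidation, 0.154 for general pluripotency, 0.11 for germline and 0.0834 for Wnt targets). Without chromosomes 6, 8 and 14, general pluripotency was not called (adjusted p = 0.0905). Acadl was lost without 5-2, and Cpt2 without 5-2 and without 12-1. The genes in parentheses had adjusted p = 0.000161 to 0.0062.

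Among lists that were not called, naive pluripotency had 3 members higher, 8 lower and 7 not called (12 alone, adjusted p = 0.467), with Klf5 (−0.88 ± 0.0905) on chromosome 14, Nanog (−0.71 ± 0.063) on chromosome 6 and Prdm14 (−0.88 ± 0.156) lower and Nr5a2 (0.72 ± 0.108) higher. Of its 18 members, 5 lie on chromosomes 6, 8 and 14. Formative and primed pluripotency had 5 higher and 10 not called (4 alone, adjusted p = 0.171), with Dnmt3b (1.65 ± 0.254), the cadherin Cdh2 (2.36 ± 0.445), the ligand Wnt8a (2.11 ± 0.428) and Sox3 (1.1 ± 0.354). In trophoblast genes 1 was higher, 3 lower and 8 not called (4, adjusted p = 0.588), with the regulator Cdx2 (2.05 ± 0.474) higher and the keratins Krt18 (−1.57 ± 0.257), Krt8 (−1.51 ± 0.382) and Krt7 (−1.65 ± 0.484) lower. Mesoderm had 3 higher and 6 not called (1, adjusted p = 0.588), which were Wnt3 (1.59 ± 0.434), Evx1 (2.08 ± 0.701) and T (2.19 ± 0.78). Neuroectoderm had 1 higher, 2 lower and 5 not called (5, adjusted p = 0.467), with Tubb3 (0.93 ± 0.268) higher and Ncam1 (−0.98 ± 0.174) and Sox1 (−1.63 ± 0.223) on chromosome 8 lower. Primitive endoderm had 4 higher, 4 lower and 8 not called (8, adjusted p = 0.916), with Lamb1 (1.29 ± 0.151) higher and Gata4 (−2.36 ± 0.365) on chromosome 14 lower. The median of that list was −0.01 and its mean −0.17, while the test pointed up. The fibroblast feeder list had 2 higher, 3 lower and 3 not called (5, adjusted p = 0.588), with Tagln (−3.3 ± 0.519) and Col1a1 (−2.31 ± 0.728) lower. No gene of the 2-cell-like list was called (0 of 4, adjusted p = 0.916). For these genes the test gave adjusted p = 7.18e-05 to 0.0499.

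The TCA cycle list had 1 member higher, 7 lower and 13 not called (8 alone, adjusted p = 0.16), with Idh2 (−0.89 ± 0.127), Sucla2 (−0.83 ± 0.0685) on chromosome 14 and Suclg2 (−1.06 ± 0.202) on chromosome 6 lower. Nuclear OXPHOS had 10 higher, 4 lower and 63 not called (11, adjusted p = 0.386). Glycolysis had 4 higher, 4 lower and 12 not called (8, adjusted p = 0.588), with the glucose transporter Slc2a3 (−1.17 ± 0.0986) on chromosome 6 lower and Pkm (0.48 ± 0.0669) higher, and its median of 0.12 and the test pointed up while its mean was below 0. FGF-MAPK targets had 2 higher, 1 lower and 11 not called (3, adjusted p = 0.293), which were Egr1 (2.07 ± 0.372), Myc (1.33 ± 0.358) and, lower and on chromosome 14, Spry2 (−0.7 ± 0.129). The LIF-STAT3 targets had 3 higher, 2 lower and 7 not called (5, adjusted p = 0.975), a median of −0.09, a mean of 0.05 and a test pointing up. The p53 targets had 2 higher, 1 lower and 12 not called (3, adjusted p = 0.588), with Sesn1 (−0.72 ± 0.103) lower. In the ATF4 stress response 6 were lower and 10 not called (6, adjusted p = 0.205), among them Ddit3 (−1.35 ± 0.282) and Atf3 (−2.4 ± 0.506). TFIIH subunits had 5 higher and 5 not called (6, adjusted p = 0.171), among them Gtf2h1 (0.34 ± 0.0869). The ERR family and cofactors had 3 higher and 8 not called (3, adjusted p = 0.467), among them Crebbp (0.46 ± 0.0959) and Med1 (0.31 ± 0.0698). Cell cycle and replication had 3 higher and 17 not called (2, adjusted p = 0.223), among them Pcna (0.32 ± 0.0744). Imprinted genes had 3 higher, 5 lower and 9 not called (8, adjusted p = 0.975), with Peg3 (1.2 ± 0.199) higher and Plagl1 (−1.48 ± 0.297) lower. The median of the imprinted list was −0.25 and its mean −0.05, while the test pointed up. Single genes were called at adjusted p = 4.98e-05 to 0.0143.

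KO_ERRb_wt against KO_mock asked what wild-type ERR beta restored. Several of the genes lost most strongly in the knockout returned. Hdac7 rose from 0.868 ± 0.188 to 7.51 ± 2.24 CPM, near the 8.08 ± 1.54 CPM of WT_mock, and Cpt1b from 2.7 ± 0.5 to 10.6 ± 4.28 CPM (n = 2 clones each). The Wnt antagonist and Wnt target Dkk1 fell (−1.99 ± 0.279, adjusted p = 0.00605). Esrrb reads rose (0.60 ± 0.0739, adjusted p = 0.00377), a call lost without 12-1 (adjusted p = 0.0677), 12-3 (adjusted p = 0.0554) and 8-3 (adjusted p = 0.056). Cpt1b was lost without the same clones, and Dkk1 without 12-1 and 8-3. In all, 163 genes were higher and 119 lower, of which 73 and 40 changed at least 2-fold, and 29 of the called genes were on chromosomes 6, 8 and 14 against 253 elsewhere. Only 8 genes were called without 12-1, 29 without 12-3 and 22 without 8-3.

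Besides Hdac7 (3.11 ± 0.393), the largest increases were in Klhdc7a (2.68 ± 0.483), the zinc finger factor Zfp521 (2.36 ± 0.348) and Camk2n1 (2.24 ± 0.347). The peptidylarginine deiminase Padi2 (2.11 ± 0.348), the membrane metalloendopeptidase (neprilysin) Mme (1.99 ± 0.185), Cpt1b (1.98 ± 0.363), Ndrg2 (1.91 ± 0.254) on chromosome 14 and the fatty acid desaturase-like Fads6 (1.82 ± 0.274) followed. The largest decreases were in the ESC-expressed Ras Eras (−2.67 ± 0.346), the serine/threonine kinase Pim2 (−2.41 ± 0.241), Pde2a (−2.1 ± 0.266) and the potassium channel Kcnd1 (−2.05 ± 0.248). The actin regulator Was (−2 ± 0.308), the nucleotide receptor P2ry2 (−1.7 ± 0.251), Plcxd1 (−1.61 ± 0.195), Kitl (−1.55 ± 0.219), the collagen-binding integrin Itga1 (−1.49 ± 0.289) and the egg coat gene Zp3 (−1.43 ± 0.264) also fell. Eras, Pim2, Kcnd1 and Was lie close together on the X chromosome, at 7924276, 7878306, 7823759 and 8081466, and were part of a wider block. Of 37 genes tested from 7 to 8.5 Mb (bounds set after these genes were seen), 18 were lower and 0 higher, with a median of −0.84, and 18 of the 37 were below WT_mock. In KO_mock against WT_mock 18 were higher and 4 lower (median 0.234), and in KO_ERRg_wt against KO_mock 2 were higher and 14 lower (median −0.265). Of 26 called genes on the whole X chromosome, 21 were lower. Of the 20 genes meeting the rule only Mme and Pim2 were called whichever clone was left out, and 2 were called without 12-1, 8 without 12-3, 6 without 8-3 and 20 without 8-4. Values of adjusted p = 0.0011 to 0.0306 applied to the genes above.

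Fatty acid oxidation was the only list called (higher, adjusted p = 0.00569, 1 member higher and 17 not called, 3 alone), with an adjusted p = 0.796 with an estimated correlation and 0.0812 without 8-3. In lists that were not called, naive pluripotency had Nanog (0.33 ± 0.0628) higher and 17 not called (4 alone, adjusted p = 0.409), and general pluripotency had the DNA dioxygenase Tet1 (−0.28 ± 0.0581) lower and 14 not called (6, adjusted p = 0.155). Wnt targets had Bmp4 (1.47 ± 0.224) on chromosome 14 higher, Dkk1 (−1.99 ± 0.279) lower and 10 not called (4, adjusted p = 0.171), and with chromosomes 6, 8 and 14 left out the list was lower (adjusted p = 0.0162). Single called members of other lists were the endoderm factor Sox7 (3.85 ± 0.64) on chromosome 14, Idh2 (0.69 ± 0.127), Slc2a3 (0.48 ± 0.0975) on chromosome 6, Egr1 (−1.63 ± 0.359) and the imprinted growth factor Igf2 (−2.3 ± 0.495), and each of the members named here but Dkk1 was lost without 12-1, without 12-3 and without 8-3. Genes given here with a standard error had adjusted p = 0.00605 to 0.0474.

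KO_ERRb_wt against WT_mock asked how far the rescued cells still differed from wild-type cells. The germline list stayed below WT_mock, with 5 of its 14 members called and no call with an estimated correlation (adjusted p = 0.343 with an estimated correlation). The imprinted transcript H19 was at 2.21 CPM against 40 CPM (n = 2 clones each). Esrrb reads were lower than in WT_mock (−0.47 ± 0.0736, adjusted p = 0.00375), a call lost without 5-2 (adjusted p = 0.0545) and without 8-4 (adjusted p = 0.0503). Of 1567 called genes 684 were higher and 883 lower, 134 and 281 of them at least 2-fold, with 432 on chromosomes 6, 8 and 14. The number was 248 without 5-2 and 287 without 8-4. The genes named by the rule were Rimbp2 (3.13 ± 0.513), Pdzrn4 (2.88 ± 0.552), the kinase-anchoring Akap6 (2.63 ± 0.446), Prickle1 (2.56 ± 0.457) and the sphingolipid enzyme Sptlc3 (2.35 ± 0.291), which were higher. Lower were H19 (−4.17 ± 0.878), the X-linked multi-copy Xlr3a (−3.5 ± 0.572), whose level is uncertain for that reason, Eras (−2.49 ± 0.345) and the meiotic Fkbp6 (−2.43 ± 0.223). Of the 10 genes meeting the rule, 4 were called whichever clone was left out, 5 were called without 5-2 and 7 without 8-4. The genes in parentheses had adjusted p = 0.000272 to 0.0165.

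The germline list was lower (adjusted p = 0.000686, 5 members lower and 9 not called, 7 alone), with Taf7l (−2.14 ± 0.285), Sycp3 (−1.02 ± 0.19), Ddx4 (−0.61 ± 0.134) and the kinase Stk31 (−0.56 ± 0.142). Wnt targets were higher (adjusted p = 0.0404, 1 member higher and 11 not called, 0 alone, adjusted p = 0.825 with an estimated correlation), with Lef1 (1.15 ± 0.327), a call lost without 5-2 (adjusted p = 0.201) and without 8-3 (adjusted p = 0.0557). Of the 5 members named here, Taf7l alone was called whichever clone was left out, 1 was called without 5-2, 4 without 5-5, 2 without 8-3 and 1 without 8-4. The number of lists called was 2, and it was 1 without 5-2, 4 without 5-5, 1 without 8-3 and 3 without 8-4. For these genes the test gave adjusted p = 0.00141 to 0.0485.

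KO_ERRb_DBDm3 against KO_mock asked what ERR beta did without DNA binding. The neural factor Olig2 rose from near 0. Of the genes most raised by wild-type ERR beta, Klhdc7a also rose here (2.55 log2, adjusted p = 0.00384) and Hdac7 was not called (adjusted p = 0.957). Spry4, the feedback inhibitor of FGF signalling, fell to 9.68 ± 12.7 CPM from 71.9 ± 3.08 CPM in KO_mock, with the 2 clones far apart. Esrrb reads were higher (0.90 log2, adjusted p = 6.85e-05). Called genes numbered 1887 higher and 2028 lower, 515 and 478 of them at least 2-fold, with 1041 on chromosomes 6, 8 and 14. The count was 1673 without 12-1, 1726 without 12-3 and 2460 without 9-8. Higher genes named by the rule were the bHLH factor Olig2 (5.62 ± 0.817), the antisense transcript Ptprtos (3.38 ± 0.531), the cation channel Trpm1 (3.31 ± 0.324), the orphan receptor Gprc5c (3.08 ± 0.414) and the laminin chain Lama3 (2.89 ± 0.295). Lower genes were H19 (−4.85 ± 1.09), the POU factor Pou2f3 (−3.15 ± 0.679), Spry4 (−2.87 ± 0.845), and the ephrin receptor Epha1 (−2.7 ± 0.415) and the focal adhesion gene Zyx (−2.54 ± 0.358), neighbours on chromosome 6. Of these 10 genes all but H19 and Spry4 were called whichever clone was left out, and 9 were called without each of the 4 clones. Single genes were called at adjusted p = 0.000133 to 0.0323.

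No list was called by camera at the assumed correlation (0 of 23), while 6 had an unadjusted p under 0.05, 1 had one with the estimated correlation, and fry called 7. Without clone 9-6, 3 lists were called. Naive pluripotency had 8 members higher, 1 lower and 9 not called (9 alone, adjusted p = 0.0831), and FGF-MAPK targets 1 higher, 5 lower and 8 not called (7, adjusted p = 0.187).

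KO_ERRb_DBDm6 against KO_mock asked what ERR beta did without TFIIH binding. The lists of oxidative metabolism and naive pluripotency were higher and FGF-MAPK targets lower, though none of them with an estimated correlation (adjusted p = 0.162 to 0.625). The FGF-responsive ETS factor Etv4 was at 3.49 ± 2.42 CPM against 155 ± 10.1 CPM in KO_mock, and Spry4 at 1.05 ± 0.269 against 71.9 ± 3.08 CPM (n = 2 clones each). Esrrb reads were higher (0.94 log2, adjusted p = 1.15e-05). In this comparison 3168 genes were higher and 3136 lower, 943 and 979 of them at least 2-fold, with 1239 on chromosomes 6, 8 and 14. Leaving out clones gave 3985 called genes without 12-1 and 4112 without 10-26. The rule named Olig2 (5.19 ± 0.816), Lama3 (4.54 ± 0.304), Ptprtos (4.15 ± 0.536), the zinc finger gene Zfp951 (3.95 ± 0.59) and the aspartic protease Napsa (3.85 ± 0.3) as higher. It named Spry4 (−6.1 ± 1.06), Etv4 (−5.48 ± 1.13), cyclin D2, Ccnd2 (−4.7 ± 0.291) on chromosome 6, the BMP-responsive Id3 (−4.5 ± 0.505) and the multiciliogenesis regulator Gmnc (−3.95 ± 0.589) as lower. All 10 were called whichever clone was left out. Values of adjusted p = 5.54e-06 to 0.00445 applied to the genes above.

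Camera called 6 lists, all of which were called whichever clone was left out. Naive pluripotency was higher (adjusted p = 0.00995, 12 higher, 2 lower, 4 not called, 14 alone), with Prdm14 (1.85 ± 0.157), Tfcp2l1 (0.64 ± 0.0713), Nanog (0.51 ± 0.0629) on chromosome 6 and Klf5 (0.54 ± 0.0903) on chromosome 14. Nuclear OXPHOS was higher (adjusted p = 0.00995, 33 higher, 11 lower, 33 not called, 49 alone), with Ndufa6 (0.71 ± 0.0728) and Atp5b (0.42 ± 0.0509) higher and Ndufa5 (−1.19 ± 0.134) on chromosome 6 and Ndufb7 (−0.61 ± 0.0696) on chromosome 8 lower, 8 members being on chromosomes 6, 8 and 14. The TCA cycle was higher (adjusted p = 0.00995, 12 higher, 3 lower, 6 not called, 16 alone), with Idh2 (1.61 ± 0.129), Idh3b (0.56 ± 0.0676), Dlat (0.47 ± 0.0687) and Sdhb (0.39 ± 0.0604). Fatty acid oxidation was higher (adjusted p = 0.00995, 11 higher, 1 lower, 6 not called, 13 alone), with Etfb (0.61 ± 0.0767), Slc25a20 (0.64 ± 0.102), Hadh (0.34 ± 0.0581) and Cpt1b (2.03 ± 0.364). FGF-MAPK targets were lower (adjusted p = 0.00995, 1 higher, 8 lower, 5 not called, 10 alone), with the ERK phosphatase Dusp6 (−1.85 ± 0.205), Egr1 (−3.26 ± 0.419), Myc (−2.95 ± 0.392) and Spred1 (−1.28 ± 0.206). The 2-cell-like list was higher (adjusted p = 0.0183, 4 of 4 members, also alone), at 0.752 CPM for Zscan4a, 0.48 for Zscan4c, 0.643 for Zscan4d and 0.301 for Usp17lb against at most 0.011 CPM in KO_mock. These genes belong to multi-copy families, so their levels are uncertain, and Zscan4c and Zscan4d were lost without 12-1 and without 12-3, Zscan4c also without 10-24. None was called with the estimate (adjusted p = 0.162 with an estimated correlation for naive pluripotency and FGF-MAPK targets, 0.621 for fatty acid oxidation and 0.625 for the others). Genes given here with a standard error had adjusted p = 1.17e-05 to 0.00128.

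KO_ERRb_AF2M6 against KO_mock asked what ERR beta did without coactivator binding. The FGF-responsive Etv4 was at 11.4 ± 9.34 CPM and Spry4 at 1.96 CPM, and the p53 target and cell-death gene Pmaip1 (Noxa) at 11.3 ± 9.36 against 112 CPM in KO_mock. Esrrb reads were higher (0.70 log2, adjusted p = 6.21e-05). Of 5659 called genes 2750 were higher and 2909 lower, 786 and 988 of them at least 2-fold, with 1234 on chromosomes 6, 8 and 14. There were 3503 called genes without 12-1 and 3605 without 12-3. Named as higher were Olig2 (5.4 ± 0.816), Ptprtos (4.7 ± 0.542), Zfp951 (4.25 ± 0.595), the multi-copy Xlr3a (4.25 ± 0.523) and Lama3 (4.19 ± 0.301), and as lower Spry4 (−5.2 ± 0.983), Etv4 (−3.77 ± 1), Ccnd2 (−3.51 ± 0.263) on chromosome 6, Pmaip1 (−3.3 ± 0.424) and the imprinted Nnat (−3.29 ± 0.545). All but Etv4 were called whichever clone was left out, and 9 of the 10 were called without 12-1 and without 32-25. The genes in parentheses had adjusted p = 1.22e-05 to 0.0173.

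Camera called 0 of 23 lists, with 6 at an unadjusted p under 0.05, 2 with the estimated correlation, and 8 called by fry. Without clone 32-31, 6 lists were called. Naive pluripotency had 9 members higher, 3 lower and 6 not called (13 alone, adjusted p = 0.084). FGF-MAPK targets had 1 higher, 6 lower and 7 not called (7, adjusted p = 0.084), and the list was lower with chromosomes 6, 8 and 14 left out (adjusted p = 0.0296).

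KO_ERRg_wt against KO_mock asked whether the related receptor ERR gamma could replace ERR beta. The lists of fatty acid oxidation, the TCA cycle, OXPHOS and naive pluripotency were higher and Wnt and FGF-MAPK targets lower, though none with an estimated correlation (adjusted p = 0.156 to 0.672). Klhdc7a rose from 0.674 ± 0.117 to 20 ± 1.73 CPM, above the 9.26 ± 3.83 CPM of WT_mock, and the DNA methylation cofactor Dnmt3l fell from 346 ± 4.76 to 13.3 ± 3.05 CPM (n = 2 clones each). Esrrb reads were higher (0.77 log2, adjusted p = 3.4e-05). Called genes were 3043 higher and 2795 lower, 1025 and 727 of them at least 2-fold, with 1039 on chromosomes 6, 8 and 14. Calls numbered 3386 without 12-1, 3819 without 12-3, 3544 without 14-1-10 and 3574 without 14-11. The rule named Klhdc7a (4.88 ± 0.493), the coatomer subunit Copz2 (4.25 ± 0.489), S100a1 (4.23 ± 0.729), Camk2n1 (3.93 ± 0.352) and Kcnt2 (3.92 ± 0.406) as higher, and H19 (−5.72 ± 1.34), Wnt8a (−5.09 ± 0.572), Dnmt3l (−4.7 ± 0.227), Ccnd2 (−4.34 ± 0.301) on chromosome 6 and Gmnc (−4.3 ± 0.64) as lower. All but H19 were called whichever clone was left out, and H19 was lost without 14-11. For these genes the test gave adjusted p = 1.32e-06 to 0.00695.

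Camera called 7 lists, each of them whichever clone was left out. Fatty acid oxidation was higher (adjusted p = 4.03e-05, 12 higher, 6 not called, 15 alone), with Cpt1b (3.69 ± 0.377), Cpt1a (1.87 ± 0.244) and Acadl (1.18 ± 0.164). Nuclear OXPHOS was higher (adjusted p = 0.000816, 34 higher, 6 lower, 37 not called, 45 alone), with Ndufb4 (0.71 ± 0.0776) and Ndufb9 (0.49 ± 0.0536). So was the TCA cycle (adjusted p = 0.00619, 10 higher, 1 lower, 10 not called, 12 alone), with Idh2 (2.06 ± 0.131). Naive pluripotency was higher (adjusted p = 0.00619, 12 higher, 3 lower, 3 not called, 15 alone), with Tfcp2l1 (1.03 ± 0.0718), Prdm14 (1.85 ± 0.158), Nanog (0.72 ± 0.0631) on chromosome 6 and Klf5 (1.01 ± 0.0911) on chromosome 14. The ATF4 stress response was higher (adjusted p = 0.00472, 10 higher, 6 not called, 11 alone), with Ddit3 (2.72 ± 0.29), Atf5 (1.07 ± 0.199), Vldlr (1.89 ± 0.356) and Trib3 (1.64 ± 0.32). Wnt targets were lower (adjusted p = 0.00182, 9 lower, 3 not called, 9 alone), with Dkk1 (−5.08 ± 0.422), Lef1 (−2.57 ± 0.362), Ccnd1 (−0.61 ± 0.0925) and the feedback gene Axin2 (−0.9 ± 0.159). FGF-MAPK targets were lower (adjusted p = 0.00182, 9 lower, 5 not called, 9 alone), with Egr1 (−3.13 ± 0.462), Dusp6 (−1.13 ± 0.202) and Myc (−2.07 ± 0.384). The 7 called lists had adjusted p = 0.156 with an estimated correlation (naive pluripotency and FGF-MAPK targets), 0.221 (fatty acid oxidation), 0.527 (Wnt targets), 0.632 (OXPHOS and TCA cycle) and 0.672 (ATF4). Single genes were called at adjusted p = 5.58e-06 to 0.00247.

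**Figure D3:**
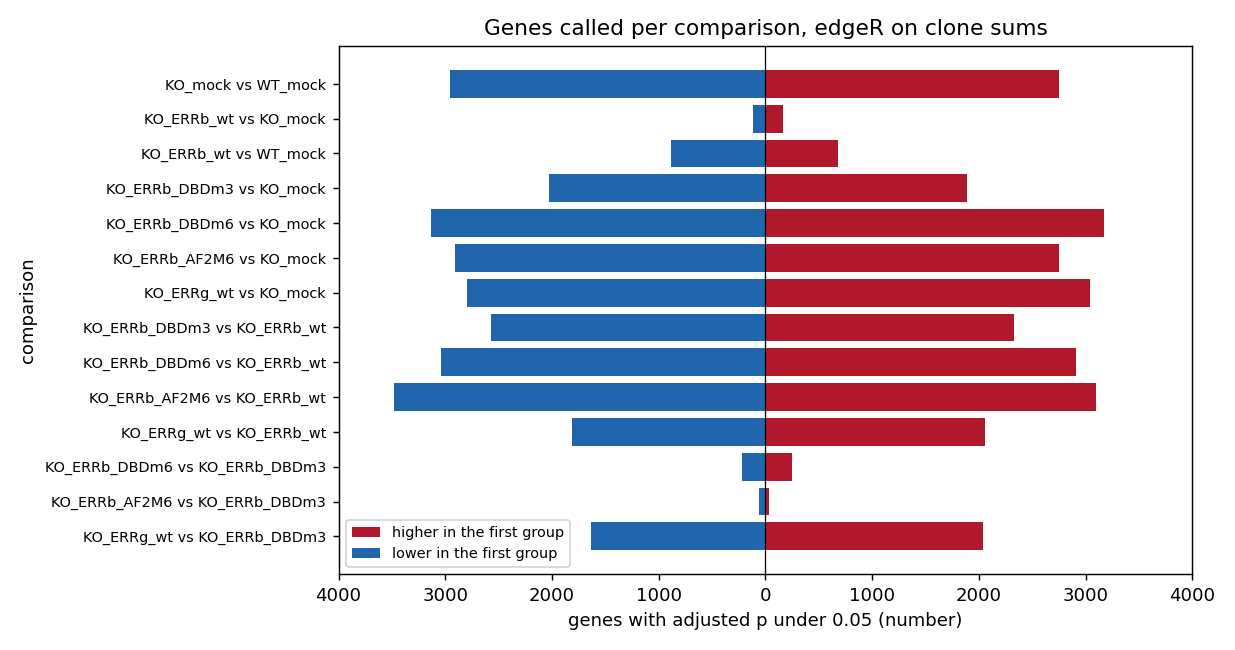
Genes called higher and lower in each of the 14 comparisons at an adjusted p below 0.05.

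Comparisons with KO_ERRb_wt asked how each mutant and ERR gamma differed from wild-type ERR beta. With the DNA-binding deficient receptor, Hdac7 was lower and the FGF receptor Fgfr2 higher. In KO_ERRb_DBDm3 against KO_ERRb_wt, 2325 genes were higher and 2567 lower (721 and 770 at least 2-fold), with 1142 on chromosomes 6, 8 and 14, and Esrrb reads were higher (0.30 log2, adjusted p = 0.0097), a call lost without 8-4 (adjusted p = 0.065) and without 9-8 (adjusted p = 0.0561). Calls numbered 2932 without 8-3. Higher genes were Olig2 (4.93 ± 0.759), Ptprtos (4.3 ± 0.573), Fgfr2 (4.23 ± 0.462), Trpm1 (4.05 ± 0.338) and the giant muscle protein gene Neb (3.88 ± 0.597). Lower genes were Pou2f3 (−3.27 ± 0.681), Hdac7 (−3.15 ± 0.391), Etv4 (−2.85 ± 0.953), the integrin Itga3 (−2.83 ± 0.268) and, on chromosome 14, Bmp4 (−2.74 ± 0.238). All 10 but Etv4 were called whichever clone was left out, and 9 were called without 8-3, without 8-4 and without 9-8. Camera called 0 of 23 lists, with 3 at an unadjusted p under 0.05, 0 with the estimated correlation, and 4 called by fry, and 3 lists were called without 9-6. Values of adjusted p = 4.41e-05 to 0.0481 applied to the genes above.

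Without TFIIH binding Spry4 and Etv4 were below KO_ERRb_wt, but so they were in the other mutants. KO_ERRb_DBDm6 had 2909 genes higher and 3041 lower (834 and 1064 at least 2-fold), with 1261 on chromosomes 6, 8 and 14, and Esrrb reads were higher (0.34 log2, adjusted p = 0.00408). The number of called genes was 3870 without 10-26. Higher genes were Zfp951 (5.41 ± 0.662), Ptprtos (5.08 ± 0.576), Xlr3a (4.94 ± 0.574), Olig2 (4.49 ± 0.756) and Lama3 (4.37 ± 0.299), and lower genes were Etv4 (−5.56 ± 1.13), Spry4 (−5.52 ± 1.04), Id3 (−4.51 ± 0.505), Ccnd2 (−4.17 ± 0.289) and Nnat (−3.86 ± 0.571), all called whichever clone was left out. Camera called 3 lists, all higher. Nuclear OXPHOS (adjusted p = 0.0155, 29 higher, 6 lower, 42 not called, 35 alone, adjusted p = 0.808 with an estimated correlation) included Cox7a2l (0.69 ± 0.0763). The TCA cycle (adjusted p = 0.0444, 11 higher, 2 lower, 8 not called, 13 alone, adjusted p = 0.808 with an estimated correlation) included Idh2 (0.92 ± 0.127) and Idh3b (0.55 ± 0.0676). The 2-cell-like list had 4 of 4 members higher, also alone (adjusted p = 0.0372, adjusted p = 0.756 with an estimated correlation). OXPHOS was lost without 8-4 (adjusted p = 0.0611) and the TCA cycle without 10-26 (adjusted p = 0.0579) and without 8-4 (adjusted p = 0.0628), which left 1 list called without 8-4. Genes given here with a standard error had adjusted p = 8.3e-06 to 0.00443.

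Without coactivator binding, Hdac7 and the FGF-responsive Spry4 and Etv4 were far below KO_ERRb_wt. Hdac7 was at 0.524 CPM against 7.51 CPM, and Fhod3, a formin of muscle sarcomeres, at 3.33 ± 1.21 against 36.7 ± 4.77 CPM (n = 2 clones each). KO_ERRb_AF2M6 had 3100 genes higher and 3476 lower (892 and 1315 at least 2-fold), with 1334 on chromosomes 6, 8 and 14, and no clone left out moved the number of calls by more than 1.5-fold. Esrrb reads were not called (0.10 log2, adjusted p = 0.278). The genes Zfp951 (5.71 ± 0.665), Ptprtos (5.63 ± 0.581), Xlr3a (5.6 ± 0.581), Fgfr2 (4.76 ± 0.468) and Olig2 (4.71 ± 0.757) were higher, and Spry4 (−4.63 ± 0.967), Etv4 (−3.85 ± 1.01), Hdac7 (−3.82 ± 0.412), Itga3 (−3.66 ± 0.284) and Fhod3 (−3.45 ± 0.221) were lower, all but Etv4 called whichever clone was left out, with Etv4 lost without 32-25. Camera called 0 of 23 lists, with 3 at an unadjusted p under 0.05, 0 with the estimated correlation, and 7 called by fry. The genes in parentheses had adjusted p = 4.86e-06 to 0.0138.

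With ERR gamma, metabolic and naive pluripotency lists were higher and Wnt and FGF-MAPK targets lower than with wild-type ERR beta, though none with an estimated correlation (adjusted p = 0.148 to 0.577). The imprinted growth regulator Grb10 was at 107 ± 16.7 against 6.98 ± 1.13 CPM and Dnmt3l at 13.3 ± 3.05 against 202 ± 30 CPM (n = 2 clones each). KO_ERRg_wt had 2055 genes higher and 1815 lower (614 and 500 at least 2-fold), with 898 on chromosomes 6, 8 and 14, and Esrrb reads were not called (0.17 log2, adjusted p = 0.121). The number of called genes was 1744 without 14-1-10, 1775 without 14-11 and 1895 without 8-4. Higher genes were Grb10 (3.94 ± 0.712), Ptprtos (3.5 ± 0.587), the meiotic Rec114 (3.48 ± 0.451), Xlr3a (3.19 ± 0.589) and Napsa (3.1 ± 0.292), and lower genes Wnt8a (−4.23 ± 0.575), Dnmt3l (−3.93 ± 0.221), Ccnd2 (−3.81 ± 0.3), the mesoderm factor T (−3.77 ± 0.902) and Nnat (−3.72 ± 0.598). All but T were called whichever clone was left out, and 9 were called without 14-1-10 and without 14-11. For these genes the test gave adjusted p = 8.97e-06 to 0.0136.

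The same 7 lists were called as in KO_ERRg_wt against KO_mock, each of them whichever clone was left out. Nuclear OXPHOS (adjusted p = 2.89e-05, 34 higher, 3 lower, 40 not called, 42 alone) was higher, and so was the TCA cycle (adjusted p = 0.00685, 10 higher, 1 lower, 10 not called, 11 alone), with Idh2 (1.38 ± 0.128). Fatty acid oxidation was higher (adjusted p = 0.00154, 10 higher, 8 not called, 10 alone), with Cpt1a (1.33 ± 0.239) and Cpt1b (1.71 ± 0.338). The ATF4 stress response was higher (adjusted p = 0.00114, 6 higher, 10 not called, 11 alone), with Ddit3 (2.42 ± 0.284). Naive pluripotency was higher (adjusted p = 0.00154, 10 higher, 1 lower, 7 not called, 13 alone), with Tfcp2l1 (0.76 ± 0.0715) and Prdm14 (1.53 ± 0.156) higher and Zfp42 (−0.56 ± 0.0886) on chromosome 8 lower. Wnt targets were lower (adjusted p = 0.00154, 1 higher, 8 lower, 3 not called, 9 alone), with Lef1 (−2.58 ± 0.361) and Dkk1 (−3.09 ± 0.477) lower and the Wnt deacylase Notum (1.28 ± 0.258) higher. FGF-MAPK targets were lower (adjusted p = 0.00416, 5 lower, 9 not called, 6 alone), with Dusp6 (−1.21 ± 0.202). They had adjusted p = 0.148 with an estimated correlation (naive pluripotency and FGF-MAPK targets), 0.516 (OXPHOS, fatty acid oxidation and Wnt targets) and 0.577 (TCA cycle and ATF4). Single genes were called at adjusted p = 6.46e-05 to 0.00497.

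The mutant and ERR gamma groups had chromosomes 6 and 8 shifted, and 3 comparisons against KO_ERRb_DBDm3 were added after this had been seen. Chromosome 8 was shifted alike in these groups, but chromosome 6 was not, and against KO_ERRb_DBDm3 its median was −0.30 log2 in KO_ERRb_DBDm6 (1 gene higher, 41 lower), −0.32 in KO_ERRb_AF2M6 (1 higher, 15 lower) and 0.27 in KO_ERRg_wt (160 higher, 35 lower). Against the DNA-binding deficient mutant, KO_ERRb_DBDm6 had more Idh2 and less of the FGF-responsive Dusp6 and the p53 target Btg2, calls that were all lost without 10-24 and without 10-26. Of 466 called genes 249 were higher and 217 lower (62 and 66 at least 2-fold), with 75 on chromosomes 6, 8 and 14, and Esrrb reads were not called (0.04 log2, adjusted p = 0.813). The number of called genes was 22 without 10-26, 36 without 10-24, 2018 without 9-6 and 1566 without 9-8. Higher genes were Xlr3a (2.49 ± 0.476), Ttc39c (2.05 ± 0.219), the serpin Serpina3m (1.92 ± 0.239), the neuronal Nsg2 (1.88 ± 0.425) and Ufsp2 (1.81 ± 0.3) on chromosome 8. Lower genes were Cfap43 (−2.8 ± 0.606), Rtkn (−2.72 ± 0.547) on chromosome 6, Id3 (−2.36 ± 0.49), Ccnd2 (−2.29 ± 0.295) on chromosome 6 and Plekhg1 (−2.04 ± 0.462). Of these 10 genes 2 were called whichever clone was left out, 2 were called without 10-24, 2 without 10-26, 9 without 9-6 and 8 without 9-8. Values of adjusted p = 0.00615 to 0.042 applied to the genes above.

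Camera called 9 lists in KO_ERRb_DBDm6 against KO_ERRb_DBDm3. Higher were the TCA cycle (adjusted p = 5.05e-06, 2 higher, 19 not called, 15 alone), with Idh2 (0.72 ± 0.126) and Dlat (0.29 ± 0.0685), nuclear OXPHOS (adjusted p = 4.99e-05, 2 higher, 75 not called, 19), with Ndufa6 (0.35 ± 0.0723) and Uqcrc2 (0.32 ± 0.0662), and fatty acid oxidation (adjusted p = 0.000317, 0 of 18 called, 6). The ATF4 response (adjusted p = 4.99e-05, 1 higher, 15 not called, 6), with the serine synthesis enzyme Phgdh (0.89 ± 0.142), glycolysis (adjusted p = 0.00328, 3 higher, 17 not called, 8), with Aldoa (0.51 ± 0.0922), Pfkp (0.39 ± 0.0803) and Hk1 (0.7 ± 0.15), and the 2-cell-like list (adjusted p = 0.0194, 0 of 4 called, 0) were higher as well. Lower were FGF-MAPK targets (adjusted p = 0.000688, 2 lower, 12 not called, 6), with Dusp4 (−1.24 ± 0.265) on chromosome 8 and Dusp6 (−0.94 ± 0.202), p53 targets (adjusted p = 0.000688, 1 lower, 14 not called, 7), with Btg2 (−1.07 ± 0.209), and general pluripotency (adjusted p = 0.0459, 1 lower, 14 not called, 2), with Utf1 (−1.04 ± 0.124). The smallest value was adjusted p = 0.154 with an estimated correlation, for FGF-MAPK targets, and the other lists had 0.414 to 0.441. Calls were lost without 9-6 for FGF-MAPK targets (adjusted p = 0.056) and the 2-cell-like list (adjusted p = 0.0902), and without 9-8 for p53 targets (adjusted p = 0.362). General pluripotency was lost without 10-24 (adjusted p = 0.0762), 10-26 (adjusted p = 0.0645) and 9-8 (adjusted p = 0.379). Of the 12 members named here, 1 was called without 10-24, 0 without 10-26, 12 without 9-6 and 9 without 9-8. Genes given here with a standard error had adjusted p = 0.00619 to 0.0446.

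Between the coactivator-binding and DNA-binding deficient mutants few genes were called with all clones, and many more without a clone of the latter. KO_ERRb_AF2M6 against KO_ERRb_DBDm3 had 34 genes higher and 64 lower (21 and 21 at least 2-fold), 22 of them on chromosomes 6, 8 and 14, with 2431 genes at an unadjusted p under 0.05, and Esrrb reads were not called (−0.20 log2, adjusted p = 0.222). The number of called genes was 19 without 32-31, 411 without 32-25, 1547 without 9-6 and 919 without 9-8. The genes Xlr3a (3.15 ± 0.483), Serpina3m (2.65 ± 0.242), Ttc39c (2.08 ± 0.219), the imprinted Usp29 (1.75 ± 0.311) and the neurofilament Nefl (1.62 ± 0.208) on chromosome 14 were higher. Lower were Ttc9 (−1.81 ± 0.223), Snx22 (−1.73 ± 0.275), the sterol-related thiolase Acat3 (−1.5 ± 0.269), Kndc1 (−1.5 ± 0.183) and the chemerin receptor Cmklr1 (−1.49 ± 0.22). Without clone 32-31, 3 of these 10 genes were called, and all 10 were called without any other clone. Camera called the TCA cycle (adjusted p = 0.0176, 1 alone), glycolysis (adjusted p = 0.0107, 4) and the ATF4 response (adjusted p = 0.0329, 0) as higher and p53 targets (adjusted p = 0.0107, 2) as lower, with 0 members called over all genes, adjusted p = 0.646 with an estimated correlation and 0 lists called by fry. All 4 lists were lost without 32-25 (adjusted p = 0.268, 0.114, 0.11 and 0.0645 in the order given) and without 9-8 (adjusted p = 0.866, 0.186, 0.765 with reversed direction, and 0.991), and the ATF4 response also without 32-31 (adjusted p = 0.0658). The number of lists called, of whatever kind, was 8 without 9-6, 2 without 9-8, 0 without 32-25 and 6 without 32-31. The genes in parentheses had adjusted p = 0.00358 to 0.036.

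KO_ERRg_wt against KO_ERRb_DBDm3 set a receptor that binds DNA against one that does not, and several genes restored by wild-type ERR beta, such as Hdac7 and Mme, led it. Mme was at 34.6 ± 3.66 against 3.32 ± 0.802 CPM, and Pde2a at 4.38 ± 0.448 against 69.4 ± 16.5 CPM (n = 2 clones each). In it 2037 genes were higher and 1638 lower (707 and 493 at least 2-fold), with 523 on chromosomes 6, 8 and 14, and Esrrb reads were not called (−0.13 log2, adjusted p = 0.203). The number of called genes was 1214 without 14-1-10 and 1269 without 14-11. Higher genes were Hdac7 (3.89 ± 0.399), Padi2 (3.68 ± 0.363), Mme (3.38 ± 0.19) and the calcium pump Atp2a3 (3.32 ± 0.29), and lower genes were Wnt8a (−4.3 ± 0.574), Pde2a (−3.98 ± 0.291), Prickle1 (−3.17 ± 0.493), the epithelial factor Grhl2 (−3.11 ± 0.351) and Dnmt3l (−2.96 ± 0.214), all called whichever clone was left out. For these genes the test gave adjusted p = 9.41e-06 to 0.00194.

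Camera called 8 lists in KO_ERRg_wt against KO_ERRb_DBDm3. Fatty acid oxidation was higher (adjusted p = 6.54e-05, 11 higher, 7 not called, 12 alone, adjusted p = 0.36 with an estimated correlation), with Cpt1b (3.06 ± 0.362), Acadl (1.24 ± 0.164) and Cpt1a (1.61 ± 0.241). Nuclear OXPHOS (adjusted p = 0.000152, 26 higher, 1 lower, 50 not called, 28), the TCA cycle (adjusted p = 0.00107, 10 higher, 11 not called, 12), with Idh2 (1.17 ± 0.127), and the ATF4 response (adjusted p = 8.62e-05, 12 higher, 1 lower, 3 not called, 16), with Ddit3 (1.96 ± 0.278) and Shmt2 (0.84 ± 0.123), were higher (each adjusted p = 0.393 with an estimated correlation). Formative and primed genes (adjusted p = 0.00152, 7 lower, 8 not called, 8), with Dnmt3b (−2.11 ± 0.261) and Fgfr1 (−0.85 ± 0.153), and Wnt targets (adjusted p = 0.00335, 1 higher, 6 lower, 5 not called, 8), with Lef1 (−2.55 ± 0.361) and Notum (−1.78 ± 0.251) lower and Bmp4 (1.52 ± 0.237) higher, were lower (each adjusted p = 0.393 with an estimated correlation). FGF-MAPK targets were lower (adjusted p = 0.0177, 3 lower, 11 not called, 2, adjusted p = 0.36 with an estimated correlation), with Etv5 (−0.49 ± 0.0869), and so were p53 targets (adjusted p = 0.00107, 1 higher, 11 lower, 3 not called, 14, adjusted p = 0.406 with an estimated correlation), with Phlda3 (−0.99 ± 0.207) and Zmat3 (−0.73 ± 0.162) lower and Sesn1 (0.63 ± 0.105) higher. Without clone 9-6 the calls of FGF-MAPK targets (adjusted p = 0.383) and Wnt targets (adjusted p = 0.0501) were lost. Phlda3 was lost without 9-8 and 14-1-10, and Zmat3 without 14-1-10 and 14-11. Single genes were called at adjusted p = 0.000318 to 0.00994.

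**Figure D4:**
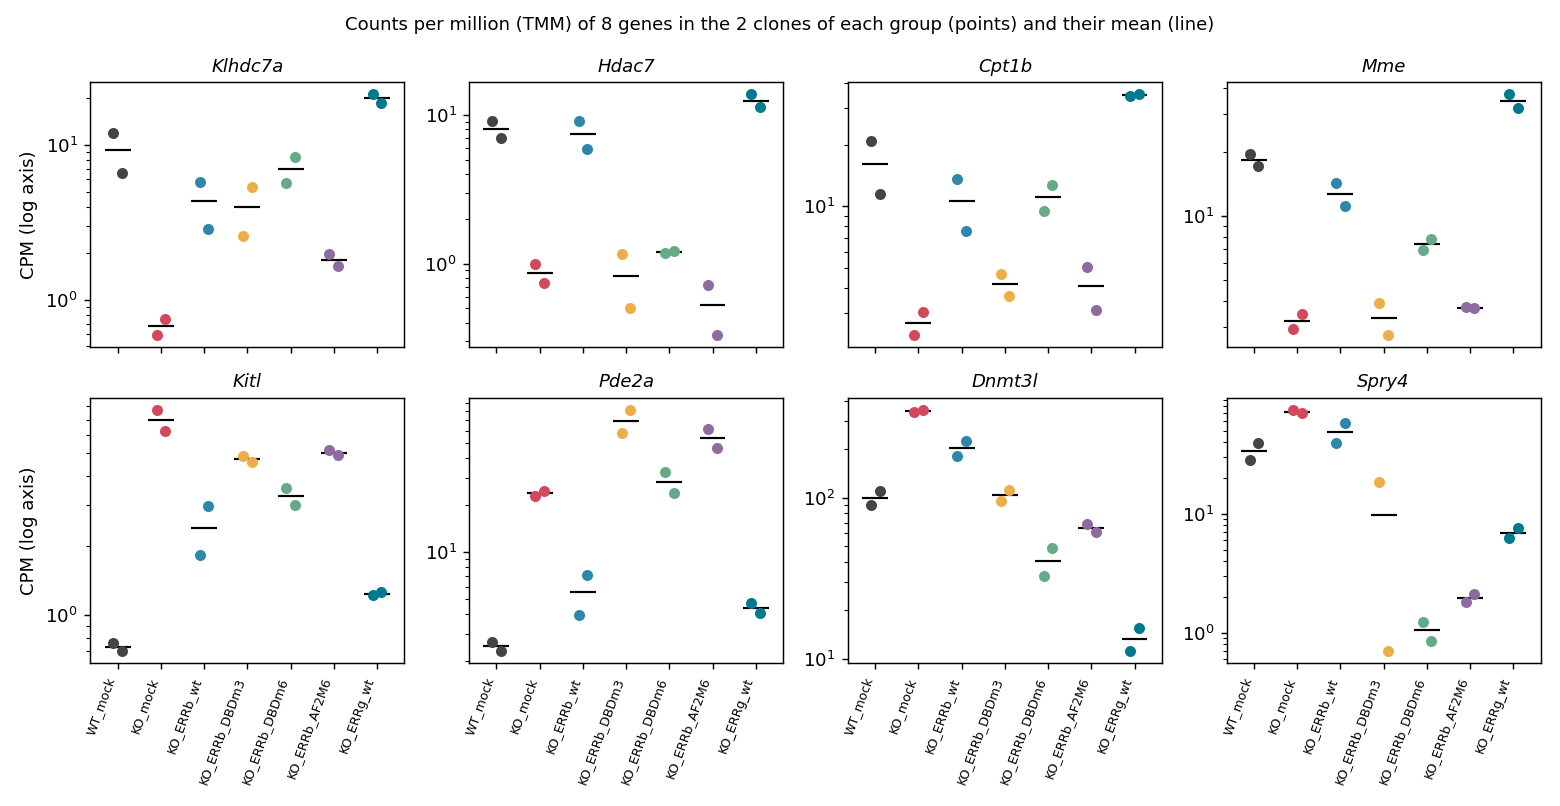
Levels (CPM, log axis) of Klhdc7a, Hdac7, Cpt1b, Mme, Kitl, Pde2a, Dnmt3l and Spry4 in each of the 14 clones, with the group mean as a line.

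Restoration was counted within the 5702 genes called in KO_mock against WT_mock. Genes called in the opposite direction against KO_mock numbered 255 (4.47%) with KO_ERRb_wt, 1055 (18.5%) with KO_ERRb_DBDm3, 2238 (39.3%) with KO_ERRb_DBDm6, 1352 (23.7%) with KO_ERRb_AF2M6 and 2939 (51.5%) with KO_ERRg_wt. Of the genes lowered in the knockout, such as Hdac7 and Cpt1b, 150, 532, 1169, 675 and 1570 were raised in that order. Independent lists would share 31.6, 366, 614, 533 and 590. Of those raised in the knockout, such as Kitl and Pde2a, 105, 523, 1069, 677 and 1369 were lowered. Independent lists would share 21.5, 366, 565, 524 and 504. Genes called further from WT_mock numbered 0, 514, 536, 861 and 159 in the same order. The median log2 change of genes lower in the knockout was 0.31, 0.12, 0.31, 0.09 and 0.51, and of genes higher in it −0.18, −0.07, −0.18, −0.05 and −0.28. Constructs simulated as unchanged gave a median of 0 genes (highest 1 of 20 draws) and medians of 0.0328 and −0.0225. The correlation of the 2 fold changes was −0.689, −0.160, −0.329, −0.108 and −0.565, beside −0.202 in the simulation. With 1 KO_mock clone defining the genes and the other as sole reference, counts do not compare. Medians of genes lower in the knockout were then 0.31 and 0.37 for KO_ERRb_wt. In the same order the others had 0.11 and 0.16, 0.32 and 0.35, 0.08 and 0.11, and 0.55 and 0.63.

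For KO_ERRb_wt the number of restored genes was 145 without 5-2, 159 without 5-5, 5 without 12-1, 21 without 12-3 and 18 without 8-3. It ranged from 293 to 1919 for KO_ERRb_DBDm3, 858 to 2225 for KO_ERRb_DBDm6, 475 to 1340 for KO_ERRb_AF2M6 and 1262 to 2925 for KO_ERRg_wt, lowest for each without 12-1.

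Within the same genes, each construct was also set against KO_ERRb_wt, with p-values adjusted over these genes alone. KO_ERRb_DBDm3 differed in 2105 genes (2025 over all genes), 1557 of them further from WT_mock and 548 nearer. KO_ERRb_DBDm6 differed in 2392 (2355), 1199 further and 1193 nearer, KO_ERRb_AF2M6 in 2786 (2713), 2019 further and 767 nearer, and KO_ERRg_wt in 1821 (1717), 391 further and 1430 nearer. The median change toward WT_mock was −0.14 for KO_ERRb_DBDm3, below 0 by less than 0.01 for KO_ERRb_DBDm6, −0.17 for KO_ERRb_AF2M6 and 0.13 for KO_ERRg_wt. With 1 clone left out in turn these numbers ranged from 954 to 3236, 1003 to 1956, 1215 to 2654 and 894 to 1612 in the order given.

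The 255 genes restored by KO_ERRb_wt, 150 raised and 105 lowered, with 27 of them on chromosomes 6, 8 and 14, were then compared between the other groups, a set chosen after the data were seen. They include Hdac7, Klhdc7a, Cpt1b, Mme and Kitl. Of the lowered genes, 13 lie in the X-linked block, Pim2, Kcnd1 and Tfe3 among them. Against KO_ERRb_DBDm3, which shares no library with the choice of these genes, KO_ERRb_DBDm6 moved 83 toward and 7 away from the direction of wild-type ERR beta (list alone, 38 called over all genes, 36 of them toward), with a median of 0.25 and 210 genes on the side of wild-type ERR beta. KO_ERRb_AF2M6 moved 12 toward and 10 away (3 and 2), with a median of −0.01 and 125 genes on that side, and KO_ERRg_wt 208 toward and 1 away (202 and 201), with a median of 0.87 and 247 genes. Without that block 242 genes were left, with 200, 115 and 235 on that side. When a clone was left out the set was chosen anew and changed in size, so these counts do not compare directly. The number of genes toward wild-type ERR beta was then 3 to 278 in KO_ERRb_DBDm6, 0 to 115 in KO_ERRb_AF2M6 and 5 to 783 in KO_ERRg_wt.

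**Figure D5:**
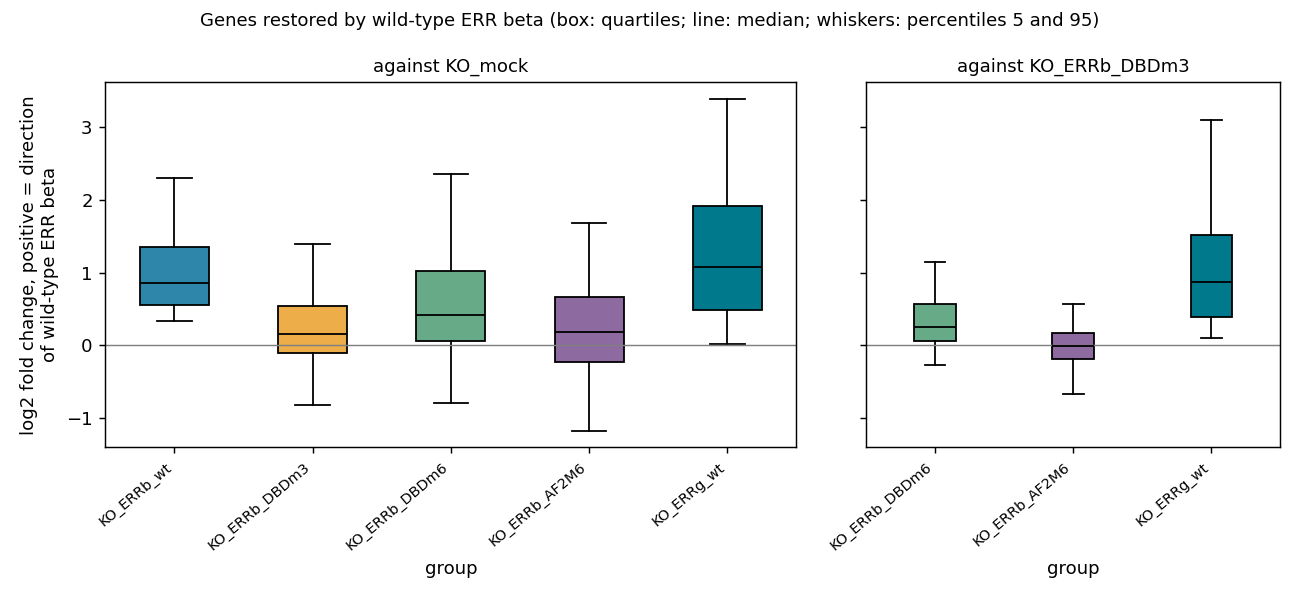
Change of the 255 restored genes, signed so that the direction of wild-type ERR beta is positive, against KO_mock (left, 5 constructs, sharing the KO_mock clones with the choice of the genes) and against KO_ERRb_DBDm3 (right, 3 constructs). Boxes are quartiles and whiskers are percentiles 5 and 95.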

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

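Of 24 tests for single deviating libraries over 4 measures, 1 stood out: Esrra was at 25.9 CPM in the second library of AF2M6 clone 32-25. About 1 in 20 such groups would hold one by chance. The other unexpected values were shifts of whole chromosomes against WT_mock. Chromosome 14 shifted by −0.617 in KO_mock, −0.586 in KO_ERRb_wt, −0.569 in KO_ERRb_DBDm3, −0.516 in KO_ERRb_DBDm6, −0.567 in KO_ERRb_AF2M6 and −0.545 in KO_ERRg_wt. In the groups KO_ERRb_DBDm3, KO_ERRb_DBDm6, KO_ERRb_AF2M6 and KO_ERRg_wt, chromosome 6 shifted by −0.673, −0.923, −0.94 and −0.358 and chromosome 8 by −0.498, −0.468, −0.503 and −0.522.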

How the results depend on the processing

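Of 503 recomputed values of 40 results, 282 were within 1.5-fold of the reported value and 221 were not. No called gene reversed direction in any comparison, and of 12895 values of the named genes 11329 kept direction and call. The only 2 reversals were of Esrrb in DBDm6 against DBDm3, which was not called: −0.0594 without 9-6 (adjusted p = 0.637) and −0.0211 without 10-26 (adjusted p = 0.949), against 0.138 without 9-8. Of the called genes, voom, DESeq2 and a fit of the 2 groups alone also called 5350, 5372 and 5633 of 5702 in KO_mock against WT_mock and 239, 273 and 280 of 282 in KO_ERRb_wt against KO_mock. The cause of the changes was not tested.

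Groups are named here by construct. With each library as a replicate, the genes called were 2678 (wild-type against KO_mock), 4635 (wild-type against WT_mock), 6436 (DBDm3 against KO_mock), 3273 (DBDm6 against DBDm3) and 1942 (AF2M6 against DBDm3). Restored genes were then 2276, 2341, 3743 and 2594 for wild-type, DBDm3, DBDm6 and AF2M6, genes differing from wild-type ERR beta 4217, 4545, 4844 and 2954 for DBDm3, DBDm6, AF2M6 and ERR gamma, and genes toward it 706, 133 and 1517 for DBDm6, AF2M6 and ERR gamma. Differences between the replicate numbers correlated at −0.388 to 0.764 over 66 clone pairs (median 0.0103, 26 above 0.1), so a replicate effect shared by some clones is not excluded. With the numbers as blocks and ERR gamma left out these values were 2508, 4429, 6287, 3099 and 1805, then 2151, 2286, 3634 and 2509, then 4114, 4428 and 4723, then 674 and 128. With voom (clone correlation 0.415) the moved values were 738 (wild-type against KO_mock), 2570 (wild-type against WT_mock), 1367 and 544 (DBDm6 and AF2M6 against DBDm3), 650 restored by wild-type, and 182, 29 and 495 toward it. With DESeq2 they were 932, 1269 and 554 called (wild-type against KO_mock, DBDm6 and AF2M6 against DBDm3), 811 restored, and 212, 34 and 613 toward. With only the 2 groups compared they were 1563 (wild-type against KO_mock), 287 and 791 (DBDm3 against KO_mock and wild-type), and 0, 0 and 356 against DBDm3. The counts of 0 by edgeR had 1674 and 686 genes at an unadjusted p under 0.05. Restored were 1334, 140, 3681 and 4796 (wild-type, DBDm3, DBDm6, ERR gamma), differing from wild-type 753, 3640 and 3094 (DBDm3, DBDm6, ERR gamma), and toward it 0, 0 and 713.

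A minimum log2 change of 1 left 1559, 113 and 415 genes (KO_mock against WT_mock, wild-type against each), 993, 1922, 1774 and 1752 against KO_mock, 1491, 1898, 2207 and 1114 against wild-type, and 128, 42 and 1200 against DBDm3. It left 90, 186, 451, 250 and 692 restored genes and 445, 442, 580 and 356 differing from wild-type. The split of the KO_mock clones gave 5, 319, 958, 532 and 1382 restored genes with 12-1 defining the set and 17, 302, 897, 504 and 1307 with 12-3. Without chromosomes 6, 8 and 14, chosen after the data were seen, 955 genes were called in wild-type against WT_mock, and 2, 1 and 5 lists in wild-type and AF2M6 against KO_mock and DBDm6 against wild-type. The estimated correlation left 0 lists called in every comparison, where 0 to 3 lists had an unadjusted p under 0.05 by camera in limma and fry called 0 to 13.

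Leaving out each clone gave 2283 to 4655 genes (KO_mock against WT_mock), 8 to 234 and 248 to 1451 (wild-type against KO_mock and WT_mock), 1673 to 5786, 3985 to 4560, 3503 to 4776 and 3386 to 3819 (DBDm3, DBDm6, AF2M6, ERR gamma against KO_mock), 2932 to 6154, 3870 to 4506, 4490 to 5801 and 1744 to 2826 (against wild-type), and 22 to 2018, 19 to 1547 and 1214 to 5255 (against DBDm3). Restored genes were 5 to 218, 293 to 1919, 858 to 2225, 475 to 1340 and 1262 to 2925, those differing from wild-type 954 to 3236, 1003 to 1956, 1215 to 2654 and 894 to 1612, and those toward it 3 to 278, 0 to 115 and 5 to 783. Lists called were 0 to 4, 0 to 1 and 1 to 4, then 0 to 3, 6 to 7, 0 to 6 and 7 to 8, then 0 to 3, 1 to 4, 0 and 7 to 8, then 7 to 10, 0 to 8 and 8 to 9. Lists changed direction in 10 cases, of which only ATF4 in AF2M6 against DBDm3 had been called. Of these, 9 changed without 9-8: p53 targets (adjusted p = 0.884, range 0.0248 to 0.884 over the clones) and ATF4 (0.64, range 0.01 to 0.675) in DBDm3 against KO_mock, ATF4 in DBDm3 against wild-type (0.815, range 0.00859 to 0.816), trophoblast (0.84, range 0.0366 to 0.84) and LIF-STAT3 (0.285, range 0.0197 to 0.803) in DBDm6 against DBDm3, trophoblast (0.991, range 0.0293 to 0.991), LIF-STAT3 (0.866, range 0.00103 to 0.955) and ATF4 (0.765, range 1.1e-06 to 0.765) in AF2M6 against DBDm3, and the 2-cell-like list in ERR gamma against DBDm3 (0.695, range 0.000919 to 0.695). Without 9-6 it was the 2-cell-like list in AF2M6 against DBDm3 (0.135, range 3.47e-05 to 0.705).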

Other observations

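Every test in this part was chosen after the result it concerns had been seen, except the comparison of Esrrg with Esrrb sequences and the splits of clones in the 11 first comparisons. The 4 measured Y-linked genes summed to 0.0404 CPM (2 counts) in the coactivator-binding deficient clone 32-31, to 26.6 CPM in WT_mock clone 5-2 and 27.4 CPM in DNA-binding deficient clone 9-8, to 57.2 CPM in WT_mock clone 5-5, to 55.4 and 69.2 CPM in the KO_ERRg_wt clones, and to 109 to 149 CPM in the other 8 clones. Expression from the Y chromosome therefore differed between clones of the same group, including the wild-type clones, and was lower in both KO_ERRg_wt clones than in either KO_mock clone. Spry4, an FGF feedback gene, also differed within KO_ERRb_DBDm3 (9.68 ± 12.7 CPM).

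The shifts of chromosomes 6, 8 and 14 are the first pattern. Centring removed common library size or scaling effects, which were not tested. Other chromosomes' means reached 0.13 log2 (0.20 in clone 32-31, chromosome 1). Copy number fits: of 568 windows of 20 neighbouring genes on the shifted chromosomes, 565 (99.5%) lay below −0.2 log2. In clones chosen as unshifted it was 0 of 314, which the choice largely fixed. An action of the constructs does not explain why the 2 clones of KO_ERRb_DBDm3 differed by 0.516 log2 on chromosome 6. The knockout cells may thus have fewer copies of chromosome 14 than WT_mock, and the mutant and ERR gamma clones fewer of chromosomes 6 and 8, which no DNA measurement tested here.

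The second pattern is that genes outside these chromosomes, such as Olig2, Lama3 and Trpm1, also set the mutant and ERR gamma clones apart from KO_mock and KO_ERRb_wt. Dosage of genes on the 3 chromosomes does not directly account for the 2874 or more genes called elsewhere, and its indirect effects were not tested. Pairing KO_mock with KO_ERRb_wt, in all 4 clones above or below the other 8, separated 2425 of 13192 genes (18.4%), the most of 15 pairs. This restates the pattern without explaining it. Graded function of the constructs would not put KO_mock, without a receptor, and KO_ERRb_wt on the same side of these genes, and pairing KO_mock with KO_ERRb_DBDm3, the groups without a DNA-binding receptor, separated 187. Other pairs also separated many genes, KO_ERRb_wt with KO_ERRg_wt 1231 (9.33%) and KO_ERRb_DBDm6 with KO_ERRb_AF2M6 1007 (7.63%). Whether these follow the construct or the history of the clones was not tested. It stays open whether the mutant and ERR gamma clones derive from another subline of the knockout, since no value here tests that apart from the pattern, and part of the large counts against KO_mock may reflect such a history. Against KO_ERRb_DBDm3, chromosome 6 still differs in all 3 comparisons (medians of −0.30, −0.32 and 0.27). There, 83 of the 255 genes restored by wild-type ERR beta moved toward it and 7 away with the TFIIH-binding deficient receptor, 12 and 10 with the coactivator-binding deficient receptor and 208 and 1 with ERR gamma. This fits function left in the TFIIH-binding mutant and in ERR gamma, but the history of the clones goes with the construct. With 1 clone left out, DBDm6 against DBDm3 called 22 to 2018 genes, so this may rest on single clones.

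The third pattern is Esrrb itself, which was 0.77 log2 higher in the ERR gamma clones than in KO_mock although they carry no ERR beta construct. Reads of Esrrg counted as Esrrb are not the cause, since 0% of 6205 stretches of 50 bases of Esrrg transcripts occur in Esrrb transcripts. ERR gamma clones were −0.13 log2 from KO_ERRb_DBDm3, whose construct may add reads, so subline or other causes stay open. Transcripts of the disrupted locus may make up most Esrrb reads, so the level of Esrrb (274 CPM in KO_mock) does not measure the construct.

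Other splits of the 4 clones in a comparison could say little, since 3 splits are too few for a share under 0.05. The real split called the most genes in 1 of 3 splits in all 14 comparisons. The highest other split called 0 genes in edgeR, with 26 to 1709 genes at an unadjusted p under 0.05, except in AF2M6 against DBDm3, where it called 85 against 98.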
